A study of Mus musculus with 6 samples.

How the data were processed

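Liver tissue of C57BL/6 mice was profiled by messenger RNA sequencing in 6 libraries, 1 for each combination of 3 tissues and 2 sexes. The tissues were normal liver of wild-type mice, and hepatocellular carcinoma and precancerous liver, described as adjacent, of transgenic mice that carry the Hras12V oncogene. Males were 9 months old and females 15 months old, so sex and age cannot be told apart in these data. The labels do not say whether a library holds 1 mouse or a pool, nor whether a tumour and a precancerous library came from the same mouse. RNA was isolated with a mirVana kit and libraries were made with a stranded mRNA kit, per the labels' protocols.

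The deposited table gives a whole-number count and an FPKM value (fragments scaled to gene length and to the library total) for each of 34745 Ensembl genes in each library. TopHat2 version 2.0.9, Cuffdiff and the builds GRCm38 and mm10 are named in the submitters' processing notes, without the step each served. The strand setting of the counting is not given in the sources used here. The deposited counts were not normalized and summed to between 5996585 and 18434508 per library. The deposited FPKM values equalled the count divided by 1 gene length and the library's own count total, with a ratio between 0.99996 and 1.00004. This was checked for genes above a count minimum in both male normal liver and the library compared. For these genes the values carry no further scaling. Coordinates are those of the table. The table's gene identifiers were matched to a GENCODE mouse annotation of the same build: 34344 were found there and 27776 had the same start and end. That annotation served to measure how much of each gene's exonic sequence lies under an exon of another gene on the opposite strand, rounded to 0.1%. No gene row was left blank.

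Genes with an FPKM of at least 1 in at least 2 libraries were tested, which left 11435 genes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM normalization and an additive model of sex and tissue over all 6 libraries. A test on log2(FPKM + 1) had been laid down for a table without counts, and edgeR for a table with them. Since the table held counts, edgeR gave the main result and limma-trend (limma 3.58.1) on log2(FPKM + 1) became an alternative. The model has 2 residual degrees of freedom and its residual holds the difference of a tissue effect between the sexes. A gene that moved in 1 sex alone therefore seldom passes when it is well counted in both. A gene with few counts in 1 sex can pass mainly on the change in the other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are log2 values with their standard error (SE). A p-value measures the spread between these libraries alone.

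Single pairs of libraries have no replicates. For them the difference of log2(FPKM + 1) is given without a test, and genes at least 2-fold apart on that scale were counted; the pseudocount of 1 understates the change of low genes. A fold against a library at 0 is a lower bound, computed against a floor of 3 counts in that library, and covers counting error only. The smallest detectable level, 3 counts, was between 0.163 and 0.5 FPM (counts scaled to the library total) over the 6 libraries.

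Before the data were examined, 35 gene lists were fixed. They covered RAS genes, RAS-MAPK feedback, cell division, tumour markers, sex-biased liver genes, hepatocyte zones, metabolic pathways, stress responses, immune responses and markers of other cell types. The 29 lists with at least 5 tested members were tested with camera on the edgeR fit at a preset correlation of 0.01, with adjustment over the lists of each comparison. The same test with a correlation estimated per list gave no call for any list in any comparison. For each pair of libraries, a list's median difference was placed among 10000 random lists of the same size matched on mean expression. Genes named in the text followed a rule set in advance. For each comparison over both sexes it took the 12 genes per direction with the largest smallest difference over the matched pairs, given at least 2-fold in every pair, an FPKM of at least 5 in at least 1 library, and a gene name. For each sex it took the 5 genes per direction that differed most from the other sex. It added RAS and sex chromosome genes and, from each list, up to 4 members with the largest mean difference. Genes of multigene families (Mup, Cyp2a, Cyp2b, Cyp2c, Cyp2d, Cyp3a, Cyp4a, Sult2a, Sult3a, Serpina1, Saa, Gsta, Gstp, Ces, Akr, histone and immunoglobulin genes) share reads with near-identical copies, and their values are uncertain. Antisense genes are uncertain for the males, because their male values followed the gene on the other strand.

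The test was tried on simulated counts for 11435 genes, of which 200 were changed, in 3 runs. In the tumor vs precancerous comparison it found 59% of 2-fold and 92.3% of 4-fold changes with 6.3 false calls on average, and in the male vs female comparison 77% and 97.3% with 9.7 false calls. The simulated counts took their spread from a trend over expression. They held no spread particular to a gene and no difference of a tissue effect between the sexes. Far fewer genes were changed than were called in the data, so the figures are not rates for the real libraries. Alternatives were other filters, other pseudocounts, median-of-ratios and quantile normalization, limma with and without a trend, and each library left out in turn. Added after seeing the data were limma-trend at a pseudocount of 1, DESeq2 1.42.0, and all counts without mitochondrial genes and genes that overlap an exon on the other strand. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.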

Results

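The libraries follow liver from the normal state through precancerous tissue to hepatocellular carcinoma driven by the Hras12V oncogene, in males and in females, to describe how the sexes differ in tumour development. Each of the 6 groups holds 1 library, so no group has a replicate. Total counts were 5996585, 6891837 and 7347064 in the male normal, precancerous and tumour libraries, and 17655912, 15047022 and 18434508 in the female ones. Albumin (Alb), the main secreted protein of hepatocytes, took 5.74%, 9.55% and 13.7% of male counts and 9.07%, 10.5% and 14.0% of female counts, in the same order. Mitochondrial genes took 4.80%, 3.10% and 1.91% of male counts and 7.31%, 5.93% and 3.79% of female counts. Without mt-Co1 and mt-Co2, which were at or near 0 in males, the female shares were 3.45%, 2.82% and 2.02% and the male shares stayed the same; mt-Nd6 and mt-Nd4l, near 0 in females alone, were kept, so the shares of the sexes cannot be compared. The 95% Wilson interval of the albumin share ran from 5.722% to 5.759% in male normal liver, the smallest library; it covers counting error only, and the other intervals were of like width.

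The labelled sex of each library was checked first. Xist, which silences an X chromosome in females, stood at 41.8, 41.8 and 46.7 FPKM in the female normal, precancerous and tumour libraries and at most at 0.018 in males. The Y genes Ddx3y and Eif2s3y lay between 10.5 and 13.3 FPKM in males; Eif2s3y was listed at 0 in all females and Ddx3y was at most 0.0072. All 5 sex chromosome genes tested, Kdm5d and Uty included, matched the labels, and none of the 5 differed between tissues. The transgene's own family changed little: Hras was at 3.28, 3.27 and 3.50 FPKM in male normal, precancerous and tumour tissue and at 2.05, 2.22 and 2.84 in females. None of the 3 RAS genes passed the test between tumour and precancerous or between precancerous and normal tissue. Between tumour and normal tissue 1 of the 3 rose, with a list median of 0.26 on the log2 scale. Over all tissues 2 of the 3 were higher in males than in females (3 over the list alone), with a median of 0.42. Counts of the endogenous mouse gene need not include transcripts of the transgene, so Hras checks the genotype labels only in part.

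Tumour was compared with precancerous tissue to find what sets the carcinoma apart from the precancerous liver of the same sex and age. Fetal liver and tumour marker genes stood out. Ly6d, a surface antigen, rose from 2.34 to 290.5 FPKM in males and from 20.01 to 694 FPKM in females (log2 fold change 5.79, SE 0.46, adjusted p = 0.00318); in the GRCm38 build it lies on chromosome 15 from 74762056 to 74763620. Afp, the alpha-fetoprotein of fetal liver (chromosome 5, 90490737 to 90508907), rose from 1.16 to 93.1 and from 7.19 to 125 FPKM, and the imprinted RNA H19 from 0.255 to 15.1 and from 2.02 to 244 FPKM. Of 14 tested markers in that list, 10 rose and none fell (13 rose when adjusted over the list alone; camera adjusted p = 4.73e-07; adjusted p = 0.336 with an estimated correlation).

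Genes of the NRF2 antioxidant response rose alongside: 13 of 15 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 1.11e-06; adjusted p = 0.336 with an estimated correlation). Slc7a11, the cystine importer, rose from 0.0277 FPKM (3 counts) to 33.6 FPKM in males and from 1.28 to 30.9 in females, and the glutathione transferase gene Gsta2 from 3.14 to 137 and from 15.4 to 223 FPKM. Of 18 p53 and senescence genes 15 rose, among them the cell cycle inhibitors Cdkn2b (log2 fold change 3.93), Cdkn2a (3.52) and Cdkn1a (3.25), with 15 adjusted over the list alone (camera adjusted p = 7.74e-08; adjusted p = 0.336 with an estimated correlation). Mitosis genes rose too, 7 of the 8 tested and 8 adjusted over the list alone, with Mki67 at 2.06 and Cdc20 at 2.88 (camera adjusted p = 1.15e-05, and adjusted p = 0.336 with an estimated correlation). The list names 22 genes. A low gene reaches the level for testing more readily when both tumours are high, so the 8 may tilt toward genes that rose. Members below that level also had a higher FPKM in tumour than in precancerous tissue in both sexes. DNA replication genes rose in 5 of 15 cases, 5 over the list alone as well, Mcm2 by 1.78 and Mcm5 by 1.65 (camera adjusted p = 0.0119; adjusted p = 0.458 with an estimated correlation).

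Feedback genes of the RAS-MAPK pathway rose in 8 of 15 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.001; adjusted p = 0.458 with an estimated correlation). The phosphatase gene Dusp5 rose by 3.06 on the log2 scale, Dusp4 by 2.58, and the early response genes Ier3 and Egr1 by 3.06 and 2.65. Cholesterol synthesis genes rose in 16 of 20 cases and 17 over the list alone, led by Sqle (2.67), Hmgcs1 (2.35) and Cyp51 (2.23); the camera adjusted p was 1.79e-08, and the adjusted p = 0.413 with an estimated correlation. Of 16 genes of the unfolded protein response 10 rose (10 adjusted over the list alone), with Asns at 4.65, Trib3 at 2.97 and Ddit3 at 1.90 (camera adjusted p = 0.000251; adjusted p = 0.458 with an estimated correlation). Glycolysis genes rose in 5 of 14 cases and fell in 1 (6 and 1 adjusted over the list alone), with Pkm up by 1.73 and Pdk1 down by 1.35 (camera adjusted p = 0.0336; adjusted p = 0.625 with an estimated correlation).

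Several metabolic lists of hepatocytes went the other way. Urea cycle and amino acid breakdown genes fell in 15 of 23 cases and 18 over the list alone, and none rose (camera adjusted p = 2.25e-08; adjusted p = 0.347 with an estimated correlation): Hpd had a log2 fold change of -3.26 and Prodh of -3.42. Bile acid synthesis and transport genes fell in 11 of 17 cases and rose in 2 (13 and 2 adjusted over the list alone; camera adjusted p = 3.54e-05; adjusted p = 0.336 with an estimated correlation), with the importers Slc10a1 at -2.59 and Slco1b2 at -3.002. Pericentral genes fell in 7 of 15 cases (8 over the list alone), Cyp2e1 by 3.58 on the log2 scale; periportal genes fell in 6 of 15 and rose in 1 (8 and 2 adjusted over the list alone), Cyp2f2 at -2.14. Their camera adjusted p-values were 0.000165 and 0.00642, and adjusted p = 0.484 and 0.521 with an estimated correlation. Oxidative phosphorylation genes fell in 8 of 20 cases and 10 over the list alone, Sdha at -0.84 and Sdhb at -0.82 (camera adjusted p = 0.000344; adjusted p = 0.484 with an estimated correlation). Fatty acid oxidation genes fell in 5 of 19 cases and rose in 1 (6 and 1 adjusted over the list alone), and Fgf21, the riser, had a log2 fold change of 3.60 (camera adjusted p = 0.0492; adjusted p = 0.686 with an estimated correlation). Of 17 fatty acid synthesis genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), Scd2 at 3.48 and Srebf1 at -1.43, with a camera adjusted p of 0.558.

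Growth hormone and sex steroid signalling genes fell in 10 of 18 cases and rose in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000136; adjusted p = 0.347 with an estimated correlation). Igf1 had a log2 fold change of -3.21 and Igfals, which carries it in blood, of -3.87, while the binding proteins Igfbp1 and Igfbp3 rose by 4.02 and 2.77. Igfbp1 reached 1327 FPKM in the male and 2101 FPKM in the female tumour. Complement and coagulation genes fell in 6 of 22 cases and rose in 1 (9 and 2 adjusted over the list alone; C9 at -1.84, Mbl1 at -1.71; camera adjusted p = 0.00547; adjusted p = 0.458 with an estimated correlation). Acute phase genes rose in 1 of 19 cases and fell in 2 (0 and 2 adjusted over the list alone), Orm3 at -4.68 and Crp at -1.86, with a camera adjusted p of 0.44.

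Markers of other cell types did not move as 1 block. Stellate cell and matrix genes rose in 11 of 18 cases and fell in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 4.27e-05; adjusted p = 0.336 with an estimated correlation), with Acta2 at 3.50 and Col1a1 at 3.60. Macrophage and Kupffer cell genes fell in 10 of 14 tested cases and rose in 1 (11 and 1 adjusted over the list alone). The camera adjusted p was 1.98e-06, and 0.336 with an estimated correlation. The resident Kupffer cell markers Marco, Clec4f and Timd4 had log2 fold changes of -4.44, -2.90 and -3.92. Members below the level for testing went partly the other way. Ccr2 went from 0.217 to 1.02 FPKM in males and from 0.180 to 0.579 in females. Trem2 went from 0.142 to 0.467 and from 0.206 to 0.647, while an Itgam entry was lower in the female tumour. A loss of all macrophages cannot be read from this list. Endothelial genes fell in 7 of 16 cases and rose in 2 (9 and 2 adjusted over the list alone; Clec4g at -1.97; camera adjusted p = 0.003; adjusted p = 0.484 with an estimated correlation). Of 12 listed cholangiocyte markers 5 were tested, and 3 rose (4 over the list alone), with Spp1 at 3.73 and Sox9 at 1.83. The camera adjusted p was 0.00224, and 0.336 with an estimated correlation. Markers below the level for testing were mixed. Krt19 went from 0.497 to 0.350 FPKM in males and from 0.399 to 1.07 in females, while Cldn7 was higher in both tumours. A rise of cholangiocytes cannot be read from this list. Antigen presentation genes rose in 6 of 16 cases and 8 over the list alone, H2-Eb1 at 2.01 and Cd74 at 1.45 (camera adjusted p = 0.000945; adjusted p = 0.514 with an estimated correlation). Interferon genes rose in 4 of 18 cases and fell in 1, also over the list alone (Cxcl10 at 1.62; camera adjusted p = 0.0584). Of red blood cell genes 1 of 5 fell, also over the list alone (Hbb-bt at -0.71; camera adjusted p = 0.0231; adjusted p = 0.484 with an estimated correlation). Lists under 5 tested members had no camera test. Of 17 listed T and NK cell genes 4 were tested and 2 rose (Nkg7 at 2.56, Cd3e at 1.95). In single pairs, 2 of these 4 were at least 2-fold higher in the male tumour and 0 in the female one. No B and plasma cell gene of 3 and no neutrophil gene of 3 passed, and no pancreatic acinar gene reached the level for testing. Of 7 listed adipocyte genes 2 were tested, and both fell (Car3 at -3.48, Plin4 at -1.33). Adipoq, Plin1, Lep, Retn and Cfd had at most 2 counts in any library, so a fall of adipocytes cannot be read from this list.

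Further genes with large differences in both sexes included Pnpla5, Cdh17 and Slpi, which rose by 4.42, 5.87 and 4.26 on the log2 scale, and Gstp2 by 3.69. Among genes that fell, Upp2 went from 50.1 to 2.60 FPKM in males and from 62.1 to 3.24 in females, Ces3b from 70.7 to 5.58 and from 53.2 to 2.99, and Cyp2c44 from 208 to 16.8 and from 168 to 8.51. Mup15, Mup16, Sult2a8, Cyp2c54, Hamp2 and Orm3 fell as well, by 4.68 to 6.33 on the log2 scale. Cyp2c69 and Mup17 were lower in both tumours but missed the threshold (adjusted p = 0.167 and 0.0598). In all, 1579 genes rose and 1386 fell. The 2-fold counts were 759 higher and 538 lower in males and 679 and 555 in females; 496 genes were higher in both and 332 lower in both, against 45.1 and 26.1 if the sexes were independent. The call count fell from 2965 to 458 without the male precancerous library, to 506 without the female one and to 1731 without the female tumour. A pair within 1 sex has no replicate check.

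Precancerous tissue was compared with normal liver to find what the liver of the oncogene's carriers shows outside the tumour; this contrast sets transgenic against wild-type mice of the same age. Cholesterol synthesis genes were the lists' clearest group. Msmo1, Cyp51 and Fdps fell by 2.34, 2.40 and 2.01 on the log2 scale (adjusted p = 0.0318, 0.0481 and 0.0492). Cyp51 went from 58.2 to 8.64 FPKM in males and from 45.2 to 10.7 in females. Of 20 members 4 fell, 15 adjusted over the list alone, and none rose (camera adjusted p = 2.96e-19; adjusted p = 0.495 with an estimated correlation). Hmgcs1 and Idi1 had log2 fold changes of -2.76 and -3.17 without passing (adjusted p = 0.0593 and 0.0554). Cyp8b1, which sets the cholic acid share of bile acids, fell from 132 to 10.5 and from 121 to 17.7 FPKM (adjusted p = 0.0377). Noct, a rhythmic deadenylase gene, fell from 17.3 to 2.17 and from 27.9 to 2.54 FPKM (adjusted p = 0.0251), and Acsf2 fell by 2.47 on the log2 scale.

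Some tumour markers were already higher than in normal liver. Akr1c18 rose from 0.253 to 8.24 FPKM in males and from 0.0858 to 19.6 in females, with 2 counts in each normal library (adjusted p = 0.0492). Tff3, a secreted trefoil peptide gene, stood at 79.5 against 2.71 FPKM in males and at 65.7 FPKM in females, where normal liver was listed at 0, at least 190-fold higher (adjusted p = 0.0655). Gpc3 was at 2.71 against 0.107 FPKM in males and 36.7 against 0.110 in females (adjusted p = 0.118). Of 14 tumour markers 1 rose, 9 adjusted over the list alone (camera adjusted p = 2.82e-12; adjusted p = 0.495 with an estimated correlation). The leptin receptor gene Lepr rose from 0.412 to 10.4 and from 0.604 to 6.97 FPKM (adjusted p = 0.0377), Tnfsf10, which encodes the death ligand TRAIL, by 2.98 on the log2 scale (adjusted p = 0.0251) and Gldn by 6.27 (adjusted p = 0.0404).

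RAS-MAPK feedback genes passed in 0 of 15 cases and rose in 6 over the list alone (Spry4 higher by 1.55, Dusp6 by 1.18; camera adjusted p = 1.08e-06; adjusted p = 0.495 with an estimated correlation). No macrophage gene of 14 passed and 5 rose over the list alone (Marco higher by 1.06; camera adjusted p = 3.37e-07; adjusted p = 0.495 with an estimated correlation). Fatty acid synthesis genes rose in 5 of 17 cases and fell in 2 over the list alone, and none over all genes; Srebf1 was higher by 1.61 and Elovl6 by 1.60 (camera adjusted p = 0.000252; adjusted p = 0.665 with an estimated correlation). Fatty acid oxidation genes fell in 4 of 19 cases over the list alone and oxidative phosphorylation genes in none of 20, with camera adjusted p-values of 2.62e-05 and 0.000353 (adjusted p = 0.665 for both with an estimated correlation). Interferon genes rose in 5 of 18 cases, acute phase genes in 3 of 19 and red blood cell genes in 3 of 5 over the list alone, all with camera adjusted p-values under 0.05 (0.000252, 0.000975 and 0.00249) and adjusted p = 0.495, 0.665 and 0.665 with an estimated correlation. Growth hormone and sex steroid genes rose in 1 of 18 cases, which was Lepr, and 3 over the list alone (camera adjusted p = 0.00945; adjusted p = 0.665 with an estimated correlation). Camera also called female-biased genes upward (0.000966), male-biased genes downward (0.0151), urea cycle genes downward (0.0213) and p53 targets upward (0.0352), with adjusted p between 0.665 and 0.706 with an estimated correlation; Elovl3 and Mup12, both male-biased, fell. The other lists tested had no camera call.

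Other genes of the naming rule were Hist1h2al, listed at 0 in both normal libraries and at 7.29 and 8.44 FPKM in precancerous tissue, and Ces1b, Ifi27l2b and Apoa4, higher by 1.83 to 2.37 on the log2 scale without passing. Cyp2a4 and Pnpla3 were higher as well (adjusted p = 0.525 and 0.161). Rps3a1, a ribosomal protein gene, fell from 85.9 to 1.63 FPKM in males and from 79.1 to 2.52 in females and stayed at 2.79 and 3.72 in tumours (adjusted p = 0.0175); it was low in all 4 transgenic libraries and high in both wild-type ones, a difference in its copies between the mice was not tested, and the fold is uncertain. Aox3 was at 3.59 against 177 and at 3.35 against 45.7 FPKM, Csad at 5.70 against 83.3 and 8.66 against 37.5, and Igkv5-39 was lower in both sexes (adjusted p = 0.0554, 0.0879 and 0.0673). In all, 12 genes rose and 17 fell. At an unadjusted p under 0.05, 1807 genes passed. The edgeR count was 0 without the female precancerous library, where 865 genes had an unadjusted p under 0.05, 6 without the male normal one, 13 without the male precancerous one, 211 without the male tumour and 219 without the female tumour. DESeq2 called 368 genes, limma-trend 3, and edgeR without the filter 183.

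Tumour was also set against normal liver, the endpoints of the series. Akr1c18 rose from 0.253 to 220.5 FPKM in males and from 0.0858 to 194 in females, Tspan8 from 0.628 to 191 and from 0.426 to 123, and Scd2, a desaturase gene, from 2.29 to 129 and from 1.77 to 109. Gpc3, the proteoglycan used as a marker of human liver cancer, rose from 0.107 to 99.5 and from 0.110 to 118 FPKM. Tumour markers rose in 13 of 14 cases and over the list alone as well (camera adjusted p = 1.09e-08, and adjusted p = 0.387 with an estimated correlation). Genes that fell included Car3, from 652 to 45.4 and from 390 to 26.0 FPKM, Hamp, the iron hormone hepcidin, from 1079 to 52.5 and from 1984 to 36.7, and Cyp2c29 from 594.5 to 28.3 and from 290.2 to 19.2. Cyp8b1, Ces3a, Ces3b, Sult2a8, Cyp2c54, Aox3, Mup15 and Mup16 fell in both sexes too, by 4.19 to 7.59 on the log2 scale.

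Cholesterol synthesis genes, low in precancerous tissue, stood near the normal level in tumours: 3 of 20 rose and 2 fell, also over the list alone, with Sqle at 1.197 and Idi1 at -1.35. Their median log2 fold change was -0.12 and their mean 0.09, and the camera adjusted p was 0.832. Urea cycle genes fell in 18 of 23 cases (21 over the list alone), oxidative phosphorylation genes in 15 of 20 (18), bile acid genes in 12 of 17 with 3 that rose (the same over the list alone), and fatty acid oxidation genes in 12 of 19 with 1 that rose (13 and 2 adjusted over the list alone). NRF2 targets rose in 12 of 15 cases (13 over the list alone) and p53 and senescence genes in 14 of 18 (14, and 1 fell). RAS-MAPK feedback genes rose in 12 of 15 with 1 that fell (the same over the list alone), and mitosis genes in 8 of the 8 tested (8). Camera adjusted p-values of these 8 lists lay between 1.05e-08 and 0.000472, and adjusted p between 0.387 and 0.579 with an estimated correlation. Stellate cell and matrix genes rose in 11 of 18 cases and fell in 2 (13 and 2 adjusted over the list alone). Of 12 listed cholangiocyte genes 5 were tested and 4 rose (4 over the list alone). Macrophage genes fell in 6 of 14 cases and rose in 1 (8 and 1 adjusted over the list alone), and endothelial genes fell in 8 of 16 and rose in 3 (the same over the list alone). Their camera adjusted p-values were 0.000415, 0.00523, 0.00523 and 0.0365, and adjusted p = 0.387, 0.409, 0.387 and 0.63 with an estimated correlation. The red blood cell list had a median of 0.2 and a mean of -0.18 and no call. In all 1978 genes rose and 1841 fell; 610 were at least 2-fold higher in both sexes and 452 lower, against 71.0 and 47.6 if the sexes were independent. The count of 3819 fell to 1923 without the female normal library, and to 2377, 2453 and 2522 without the male precancerous, female precancerous and female tumour libraries.

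The sexes were then set side by side within each tissue, which the study's question on sex disparity asks for. In normal liver the sex-biased genes were far apart, and the gap narrowed with each tissue. The median male to female difference of 21 male-biased genes was 5.27 in normal, 3.83 in precancerous and 0.69 in tumour tissue, in log2(FPKM + 1), and that of 25 female-biased genes was -5.20, -2.56 and -0.03. Mup7, a major urinary protein gene of males, stood at 8097, 1804 and 19.97 FPKM in male normal, precancerous and tumour tissue and at most at 1.06 in females. Mup1, Mup12, Mup14 and Moxd1 also ended in the male tumour at or below 12.7 FPKM, from 729, 752, 2053 and 37.5 in male normal liver. Elovl3 stood at 357, 6.02 and 0.182 FPKM in males. Most female-biased genes were lower in the female tumour than in female precancerous tissue: 19 of 25 were at least 2-fold lower and 2 at least 2-fold higher. A1bg stood at 366, 334 and 0.625 FPKM in female normal, precancerous and tumour tissue, and Cyp3a41a at 44.6, 60.3 and 0.579. Sult3a1 stood at 115, 149 and 1.04, and Cyp2c69 at 339, 385 and 4.14.

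**Figure D1:**
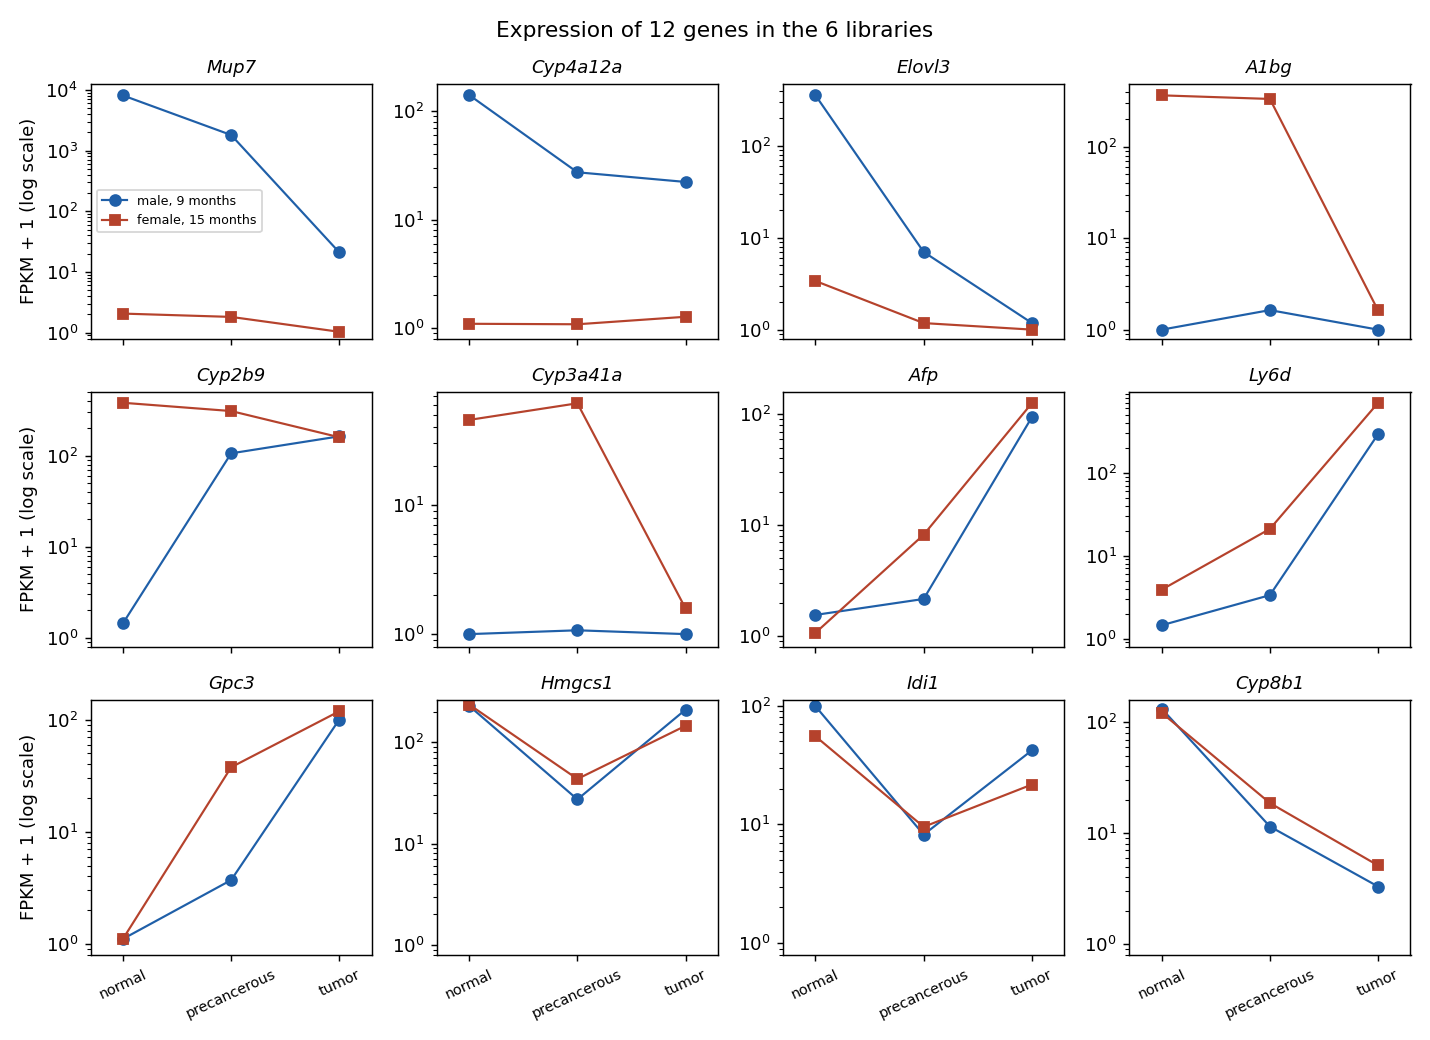
FPKM + 1 on a log scale of 12 genes in normal, precancerous and tumour liver; each point is 1 library, with males of 9 months as blue circles and females of 15 months as red squares. Mup7 goes from 8097 to 19.97 FPKM in males, A1bg from 366 to 0.625 in females, and Hmgcs1 is lowest in precancerous tissue in both sexes.

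Several female-biased genes were higher in male precancerous than in male normal liver. Cyp2b9 stood at 0.445, 105 and 162 FPKM in male normal, precancerous and tumour tissue, against 381, 309 and 159 in females. Cyp2a4 stood at 0.960, 144 and 4678 FPKM in males and 434, 1564 and 4556 in females. Hamp2 and Cyp2c69 were at 1.49 and 0.471 FPKM in normal, 54.6 and 111 in precancerous and 1.39 and 7.46 in tumour tissue of males. Of 297 list medians over single pairs of libraries, 181 lay outside the central 95% of their matched random lists. An extreme percentile was thus common here and does not set a list apart by itself. The median of the female-biased list in males was 1.5 between precancerous and normal tissue, above all 10000 matched random lists. In females it was 0.23, at the 99.99th percentile, and between female tumour and precancerous tissue -3.37. The male-biased list had medians of -1.24 and -2.37 in males and 0.01 and -0.08 in females for these 2 steps. In the step to tumour, 14 of its 21 members were at least 2-fold lower and 1 higher in males. In females 3 were lower and 4 higher, so the calls over both sexes for this list may rest mainly on the males. In the test over both sexes, 11 of 21 male-biased genes fell between precancerous tissue and tumour and none rose (12 over the list alone; camera adjusted p = 0.00513; adjusted p = 0.625 with an estimated correlation), and 5 of 25 female-biased genes fell and 1 rose (the same over the list alone; camera adjusted p = 0.0407; adjusted p = 0.721 with an estimated correlation).

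Other genes set the sexes apart in the tumour. Spink1 and Pnliprp1, genes of the exocrine pancreas, reached 138 and 58.9 FPKM in the male tumour against 8.61 and 1.24 in the female one. H19 was at 15.1 FPKM in the male and 244 in the female tumour. In females alone, Mup20 went from 20.7 to 156 FPKM and Cyp2d9 from 17.1 to 90.5 between precancerous tissue and tumour, toward the male tumour's 1722 and 146. Serpinb1a was at 1.23 in female precancerous and 13.9 in female tumour tissue. In female normal liver, Cyp4a14 was at 412 FPKM against 82.2 in precancerous tissue, and the immunoglobulin genes Igkc, Igha and Ighv1-53 were at 404, 33.5 and 27.8 against 33.9, 3.88 and 0.757. The serum amyloid genes Saa1, Saa2 and Saa3 stood at 2002, 1658 and 79.8 FPKM in male normal liver against 32.8, 27.0 and 3.52 in female normal liver. Genes at least 2-fold apart between the sexes numbered 1258, 1024 and 942 in normal, precancerous and tumour tissue. Without mitochondrial genes and genes under an exon of the other strand they numbered 624, 446 and 390. None of these single-library differences was tested.

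**Figure D2:**
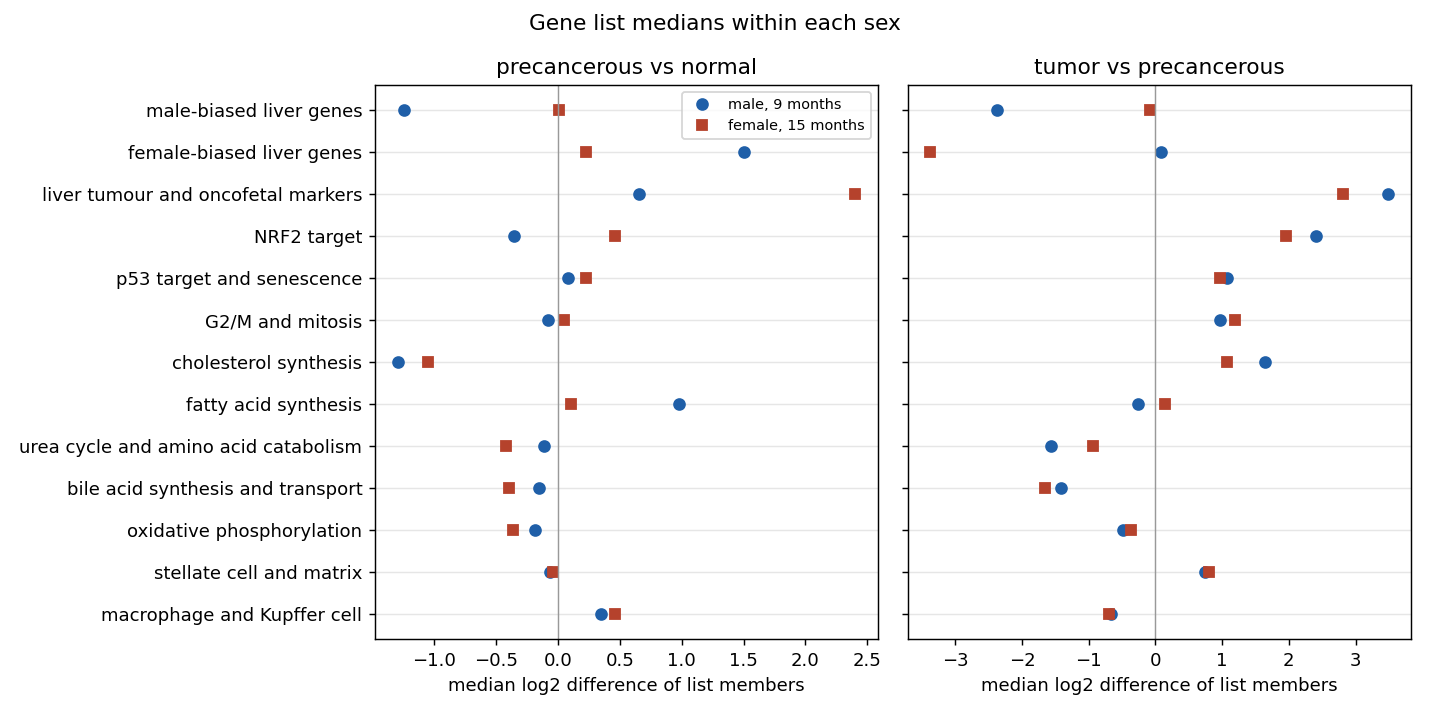
Median difference of log2(FPKM + 1) over the members of 13 gene lists, for precancerous vs normal and tumor vs precancerous tissue; each point is 1 pair of libraries, blue circles for males and red squares for females. Cholesterol synthesis genes have medians of -1.29 and -1.05 in the first step and 1.64 and 1.07 in the second, while the female-biased list moves in different steps in the sexes.

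Over all tissues, male and female libraries differed in 4270 genes, 2187 higher and 2083 lower in males. Male-biased liver genes were higher in males in 15 of 21 cases (18 over the list alone), Cyp4a12a at 139, 26.2 and 21.2 FPKM in the 3 male tissues against at most 0.269 in females (camera adjusted p = 1.16e-14; adjusted p = 0.815 with an estimated correlation). Female-biased genes were lower in males in 7 of 25 cases, also over the list alone (camera adjusted p = 3.39e-06; adjusted p = 0.815 with an estimated correlation), among them Sult2a2 and the transcription factor gene Cux2. Stellate cell and matrix genes were lower in males in 12 of 18 cases (13 over the list alone), macrophage genes in 9 of 14 with 1 higher (12 and 1 over the list alone), interferon genes in 10 of 18 (11) and antigen presentation genes in 10 of 16 (12). Dcn, C1qa, Irf7 and H2-Ab1 had log2 fold changes of -0.99, -1.18, -1.38 and -1.73. These 4 lists had camera adjusted p-values of 7.3e-06, 0.000221, 0.000615 and 0.00262, and adjusted p = 0.388, 0.388, 0.388 and 0.815 with an estimated correlation. Endothelial genes were lower in males in 8 of 16 cases (9 over the list alone) and fatty acid oxidation genes in 6 of 19 (6), while oxidative phosphorylation genes were higher in males in 8 of 20 cases and lower in 1 (8 and 2 over the list alone). Their camera adjusted p-values were 0.0125, 0.0403 and 0.0184, each with adjusted p = 0.815 with an estimated correlation. The acute phase list had a median of 0.06 and a mean of 0.28 against a camera direction of down, and the complement list a median of -0.24 and a mean of 0.17; neither had a call.

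Part of this difference followed how the genes lie on the genome. Sardhos, an antisense gene, stood at 69.9, 78.3 and 30.3 FPKM in male normal, precancerous and tumour tissue and was listed at 0 in females, at least 49.3-fold higher. Snx22 and Fam221b were at 23.1 FPKM or more and at 9.70 or more in males and at most at 0.234 and 0.0111 in females. Genes were then counted that were called between the sexes and at least 8-fold higher in males on counts summed over the 3 tissues. They made up 59.8% of 341 tested genes with at least 50% of their exonic bases under an exon of the other strand. Of 7604 genes with none they made up 0.93%. The mitochondrial gene mt-Nd6 was at 3798 FPKM in male and 4.80 in female normal liver and mt-Nd4l at 134 and 0. Of other mitochondrial genes, mt-Co1 was listed at 0 in all 3 male libraries and at 21500, 17280 and 9344 FPKM in females, at least 35400-fold lower in males, mt-Co2 was at most at 0.244 in males against 4733 or more, and mt-Atp8 at most at 0.818 against 26.3 or more. mt-Nd4 and mt-Cytb lay between 2945 and 9201 FPKM in all 6 libraries. The genes Ubb, H3f3c, Hist2h2aa2, Rpl29 and Rps18-ps3, which have close copies, were lower in males with log2 fold changes from -3.84 (H3f3c) to -1.88 (Rpl29), and Ecm1 at -1.86.

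**Figure D3:**
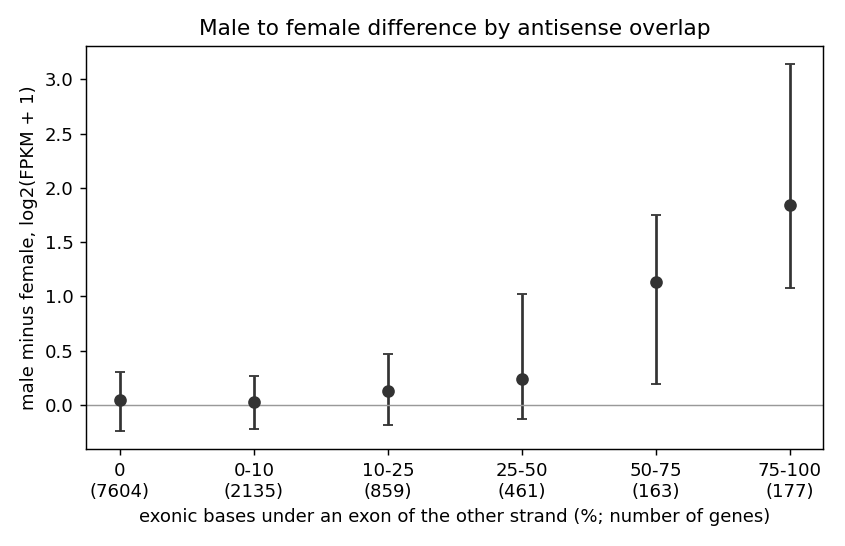
Male minus female difference in log2(FPKM + 1), averaged over the 3 tissues, against the share of exonic bases that lie under an exon of the other strand, with the number of genes in parentheses; points are medians over genes and bars run from the first to the last quartile. The median is 0.04 for 7604 genes with no overlap and 1.84 for 177 genes with 75% to 100%.

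Without mitochondrial and overlapping genes, 2440 genes were called between the sexes, 1099 higher and 1341 lower in males. The count over all genes was 762 without the male precancerous library, 847 without the female precancerous one, 2134 without the female normal and 2176 without the male normal one. Limma-trend gave 2571 higher and 1507 lower, and limma-trend after quantile normalization gave 1739 and 2401. Age and depth differ with sex here, so these differences cannot be assigned to sex.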

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

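The values below moved in opposite directions in the 2 sexes. No difference was tested, because each sex has 1 library per tissue, and the 0.5 limit for list medians was chosen after their values were seen. Differences are of log2(FPKM + 1), males first.

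Between tumour and precancerous tissue, 8 genes were at least 2-fold apart in opposite directions. Among them Cyp3a16 stood at 2.26 and -4.07, Cyp2b13 at 1.41 and -4.27, Sult2a1 at 1.03 and -3.37, and the chemokine gene Cxcl14 at -1.23 and 1.60. Cyp3a16, Cyp2b13 and Sult2a1 are on the female-biased list.

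Between precancerous and normal tissue there were 15 such genes. The serum amyloid genes Saa1 and Saa2 stood at -2.54 and 1.08 and at -3.42 and 1.21. Serpina1e, an antitrypsin gene, stood at -1.52 and 5.11, Mup17 at -2.52 and 1.37, Gstp2 at -1.50 and 2.36, and Cyp2b13 at 2.21 and -1.23.

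Between tumour and normal tissue there were 36. Cyp2b13 stood at 3.62 and -5.49, Cyp2c69 at 2.52 and -6.05, Cyp2b9 at 6.82 and -1.26, and Sult3a1 at 1.03 and -5.83. Serpina1e stood at -2.99 and 4.64, Saa2 at -5.36 and 1.96, Saa1 at -4.86 and 1.52, Cyp2d9 at -2.22 and 2.36, and Mup21 at -2.23 and 2.07. Of the lists, female-biased liver genes had medians of 1.26 and -2.63, and the 3 B and plasma cell genes of 1.04 and -3.07.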

How the results depend on the processing

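Tests with DESeq2, limma-trend at a pseudocount of 1 and without overlapping and mitochondrial genes were added after seeing the data; the other settings were planned. No paired analysis was possible because each group holds 1 library and the labels link no libraries by animal; sex is a term of the model, so tissues were compared within sex. All 16 gene counts were within 1.5 times the main value under median-of-ratios scaling. With each library left out in turn, the tumor vs precancerous count ranged from 458 to 2933, precancerous vs normal from 0 (edgeR without the female precancerous library, 865 genes unadjusted) to 219, tumor vs normal from 1923 to 3241 and male vs female from 762 to 3732, with 1 residual degree of freedom fewer. The precancerous vs normal count of 29 was 183 without a filter, 9 at FPKM of at least 5, 368 with DESeq2, 10 with limma at pseudocount 0.1, and 3 with limma-trend at pseudocount 1, with quantile normalization and without a trend; the cause was not tested. At FPKM of at least 5, the counts of the other 3 comparisons were 1783, 2262 and 2314. Without overlapping and mitochondrial genes, male vs female fell to 2440, and in normal, precancerous and tumour tissue to 624, 446 and 390. Among single pairs, pseudocount 0.1 raised tumor vs precancerous to 1978 in males and 1959 in females, precancerous vs normal to 807 and 658, and male vs female to 1976, 1653 and 1431 in normal, precancerous and tumour tissue; genes in opposite directions became 34, 40 and 80. At FPKM of at least 5, tumor vs precancerous was 833 and 820, tumor vs normal 1063 and 1091, and male vs female 707, 572 and 480. Camera's 72 calls became 0 with an estimated correlation, which no list's call survived; 59 remained without overlapping and mitochondrial genes. Of 607 gene results named or drawn from lists, 13 lost and 61 gained a call with DESeq2, 50 lost it with limma-trend and up to 134 with a library left out. Directions reversed in 6, counted only where the main or the alternative result was called. A change of sign without a call in either was not counted. Without the female tumour, tumor vs precancerous was 5.57 for Cyp3a16, 4.68 for Sult2a1 and 1.15 for Cyp3a44, and tumor vs normal -2 for Cyp2d9. Tumor vs normal was 2.97 for Sult3a1 without the female normal library and 4.45 for Serpina1e without the male one. Over all libraries left out, Cyp3a16 ranged from -4.26 to 7.95, Sult2a1 from -3.69 to 4.68, Cyp3a44 from -5.16 to 1.15, Sult3a1 from -6.6 to 2.97, Serpina1e from -2.74 to 4.45 and Cyp2d9 from -2 to 2.04. An alternative for several columns per sample was not run, as each sample has 1 count and 1 FPKM column.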

Other observations

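Of the tests in this part, only those on the gene of the other strand and on clock genes were written before their result was seen; those on depth, the share of overlapping genes, tumour shares, food intake, the cholesterol list against the tumour and the splits were chosen or reshaped after it was seen.

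Clock genes were examined apart from the lists. In males, Per2, Per3, Dbp and Arntl differed between precancerous and normal liver by 1.80, 1.94, 1.73 and -1.39 in log2(FPKM + 1); in females the differences were 1.06, 0.98, 0.44 and -0.60. Nr1d1, which had been grouped with Dbp, was at -0.92 in males and -0.52 in females. Cry1, which had been grouped with Arntl, was at 1.21 and 0.51. Each moved against the median of its group, and whether it moved against its own phase was not tested. Between tumour and precancerous tissue the same genes differed by -0.19, -0.09, 0.16 and -0.08 in males and by -0.17, -0.83, -0.46 and 0.93 in females. The metallothionein genes Mt1 and Mt2 were higher in precancerous than in normal liver by 2.39 and 2.21 on the log2 scale in edgeR without passing (adjusted p = 0.33 and 0.355).

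The first pattern is the set of 519 genes called between the sexes and at least 8-fold higher in males on summed counts. Of these, 438 overlap an exon of the other strand. Library depth does not explain it: with at least 60 summed male counts, or 152 female counts to match the depth, 127 genes off the Y chromosome were at 0 in all females and 4 at 0 in all males, a ratio of 31.8. An age or sex difference in expression has no reason to follow genome position, yet genes with at least 50% overlap were 64.1 times as often 8-fold higher as genes with none. A candidate explanation is that the male reads were counted without regard to strand: over 188 gene pairs the male tumor vs precancerous difference followed that of the gene on the other strand (Spearman rho 0.8 across genes, which are not independent; the 8-fold set was given a floor of 3 counts after a first run). The 71 set members with no overlap, Mup7 and Cyp4a12a among them, 10 more that were not found in the annotation, and the absence of mt-Co1 in males are not covered by it. The male vs female split gave 4270 genes and the highest of the other 9 splits of the 6 libraries 0, so 1 of 10 splits gave as many. The model of each split held tissue but not sex. In the other 9 the difference between the sexes thus fell into the residual, which made calls unlikely from the start. Their 0 is therefore no baseline for 4270, and 10 splits are too few for a share under 0.05.

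The second pattern is the level of tumour genes in precancerous tissue. For 59 genes at least 8-fold higher in tumour than normal liver in both sexes, the rise in precancerous tissue was a median of 3.47% of the tumour's in males and 9.84% in females. Admixture of 1 share of the sampled tumour would give every gene a like percentage. In males the 90th percentile was 35.0 times the 10th, from Gsta1 at -6.41% to Hist1h2al at 101%, with 3 negative shares. The bootstrap lower bound of this ratio was 16.2 and its upper bound was infinite, because the 10th percentile, 0.44%, lies near 0. The quartiles, 1.33% and 9.27%, were apart as well. In these libraries this argues against 1 share as the whole cause. The bootstrap resampled genes and does not cover noise of single libraries or spread between mice. After a first run this test was split by sex and its reading tied to a bootstrap interval. That change left the female ratio and the rank correlation below undecided by the marks set for them. In females the ratio was 6.1 (95% bootstrap interval 4.0 to 14.4). Single genes ran from H19 at 0.79% and Spp1 at 1.26% to Lepr at 40.95% and Hist1h2al at 99.67%. The female quartiles were 5.81% and 13.99%. The whole interval lies above the ratio that a like percentage would give, so these values argue against 1 share as the whole cause here. They do so less strongly than in males. A mixed share together with a change within precancerous hepatocytes stays open. The shares ranked alike in the sexes with a Spearman rho of 0.51 (interval 0.29 to 0.69), but with a rho of -0.03 over the 10 genes at least 32-fold higher (ratios 15.2 and 5.4 there), so a programme shared by the sexes may or may not exist.

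The third pattern is the fall of cholesterol synthesis genes in precancerous tissue with near-normal levels in tumours. Tumour cells in the sample cannot give it, since the list's median lay below that of tumour against normal by 1.18 (difference -1.18). Less food intake would lower fatty acid synthesis genes too, and these had a median of 0.61, while fatty acid oxidation genes had -0.68; in single pairs the synthesis list had a median of 0.98 in males but 0.11 in females, so the values argue against it less in females. Collection at another time of day may contribute. The median of the genes grouped with Dbp minus that of the genes grouped with Arntl was 1.41 in males and 0.82 in females. A difference of 1 in both had been set as the mark, so this explanation stays open, and the value depends on how the genes were grouped. The oncogene alone separates other libraries, since the tumours carry it too and had a list median of -0.12 against normal liver; a change confined to precancerous tissue was not tested.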
